A study of Mus musculus with 40 samples.

How the data were processed

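Total RNA of mouse hypothalamus was prepared as stranded mRNA libraries (TruSeq) and sequenced as 100-base single-end reads on an Illumina HiSeq with 40 M reads planned per library, per the labels. The 40 libraries came from 36 BXD recombinant inbred lines, the parental strains C57BL/6J and DBA/2J, and the reciprocal hybrids B6D2F1 and D2B6F1, with 1 library per strain and RNA pooled from 3 to 6 hypothalami for each BXD line. Per the submitters' processing notes the tools were TopHat2, HTSeq and DESeq with the mouse assembly mm9, without parameters, roles or an annotation.

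The authors deposited 2 gene tables. The deposited raw table holds whole-number read counts for 23955 gene symbols, of which 2649 are 0 in every library, and every comparison here starts from these counts. The deposited normalized table holds a signal for 15251 gene names, read counts divided by the authors by a size factor per library, and tested on the values, 100% of them were whole multiples of the library's unit within a tolerance of 0.01. Both tables share 15249 names. Reads recovered from the normalized table were within 5% of the raw total for 13533 of these genes, but only 36.5% of single values were equal, so the tables do not hold the same counts, and the normalized one was used for alternatives only. All libraries were distinct, with pairwise correlations of log2 values from 0.970 to 0.997 and no library pair closer than counting error (lowest chi-square per gene 5.14).

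Library totals ran from 12.2 to 40.4 M counts with a median of 23.6 M. CPM are counts scaled to the library total after TMM normalization, and log2 CPM carry a prior count of 2. Per-library intervals of Fgf15 are exact Poisson 95% intervals, and the limit for a count of 0 is 3 counts. Intervals and limits cover counting error only, since PCR copies were not marked. Chromosomes and gene order came from GENCODE vM21 on GRCm38.p6, because the mm9 annotation used for the counts is not at hand, and no coordinates are given for that reason.

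Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Models were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood with robust dispersion, TMM, genes kept by filterByExpr, Benjamini-Hochberg adjusted p under 0.05) for the BXD lines against the 4 parental and F1 libraries, the 2 F1 libraries against the 38 inbred ones, and the slope on centred log2 Fgf15 over the 36 lines. DESeq2 1.42.0 was run as the other tool. On simulated data with 16198 genes edgeR recovered 95.5%, 88.1% and 100% of genes changed by 1 log2 unit in these 3 designs. It recovered 76.1%, 64.2% and 92.5% of genes changed by 0.5, with 10 to 11 false calls per design. The simulated genes were drawn independently, so these shares do not cover structure shared between genes. No paired analysis was possible, because each strain has 1 library and no library of a group is matched to another. Reciprocal and parental differences have 1 library a side and were judged by size: a parental difference needed at least 1 log2 unit and 5 CPM in either parent.

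For each gene with a mean of at least 1 CPM the 36 line values were sorted and the widest step with at least 6 lines on each side was taken. A step of at least 1 log2 unit counted as a gap. Lines were counted on each side and never averaged or compared as groups. The number expected without separate sets came from 20 simulations of negative binomial counts. In 200 simulated genes per distance the method called 0% at 1, 100% at 2 and 100% at 3 log2 units. These 200 genes were drawn from those with a dispersion under the median, with the lines parted evenly. The shares called therefore do not cover noisier genes or uneven sets of lines. Parents on opposite sides of the gap middle were tested by exact enumeration of 630 pairs of lines, one-sided, since linked genes are not independent. The F1 share was tested by exact enumeration of 703 arrangements, two-sided. Correlations across lines used 100000 permutations, and 19 correlations with Fgf15 were computed, none of which is given pooled, because an empty interval parts the lines by Fgf15.

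The 32 gene lists were written from textbook knowledge, and 604 of their 622 entries were found. Shifts were tested with camera (limma 3.58.1) with its preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in a direction without comparing them with other genes. Spread and coherence of a list over the lines were compared with 10000 random lists matched in 20 bins of expression, one-sided, with Benjamini-Hochberg adjustment over 30 lists. The median difference of a list between the parents was set against that of the 630 pairs of lines, and the sides of gap genes were compared pair by pair along each chromosome, both chosen after seeing the data. The mitochondrially encoded genes had 0 members in the table, and the blood genes had fewer than the 5 required, so neither list was tested. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did these steps and the plots.

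Named genes are Fgf15, Fgfr1 to Fgfr4, Klb, Kl and the genes known to differ between C57BL/6J and DBA/2J, then the 12 called genes with the smallest p per direction in an edgeR comparison, the 12 largest parental differences per direction, the 12 widest gaps, the 12 largest SDs at a mean of at least 5 CPM, the 5 largest reciprocal differences per direction at 5 CPM, and up to 4 members per list. Gene models numbered with Gm, Rik names, -ps and -rs names and clone names were counted but not named by rank, and 2 genes are not reported here. Alternatives were DESeq2, RLE size factors, looser and stricter filters, library size, principal components or marker scores as covariates, left-out libraries, other prior counts, gap widths and size rules, rank correlation, finer matching and the normalized table. Fits on recovered reads, fits without libraries with Ttr over 10 CPM and the fit with 4 marker scores were added after seeing the data.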

Results

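Hypothalamic mRNA was sequenced from 40 mouse strains in the basal state, with no treatment. The panel held 36 BXD lines, which are recombinant inbred lines derived from crosses of C57BL/6J and DBA/2J, together with both parental strains and both reciprocal F1 hybrids, B6D2F1 and D2B6F1. Each strain gave 1 library, and for a BXD line that library pooled the RNA of 3 to 6 hypothalami. No strain was measured more than once, so p-values of single genes measure a difference against the spread between strains. Errors given for the parents and F1 hybrids cover counting only. Variation between animals, dissections or libraries of the same strain was not measured. The series title names hypothalamic Fgf15/19, an endocrine fibroblast growth factor, as a regulator of glucagon secretion found by a genetic screen. Total counts per library ran from 12.2 M in BXD55 to 40.4 M in BXD51, with a median of 23.6 M. A count of 3, the upper limit that a count of 0 allows, corresponded before TMM scaling to 0.0743 CPM in BXD51 and 0.245 CPM in BXD55. These limits cover counting error only. The Y-linked gene Ddx3y was present in all 40 libraries at 89.9 to 152 CPM, and Xist, the X-inactivation transcript, had at most 10 reads in any of them.

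Fgf15 was transcribed at a low level in every BXD line, with 6 to 66 reads per library and a median of 22.5. Its level averaged 1.02 ± 0.559 CPM (SD, n = 36 lines) and ran from 0.230 to 2.08 CPM, an SD of 0.86 on the log2 scale where reads alone would give 0.37. C57BL/6J had 9 Fgf15 reads, or 0.356 CPM with an exact Poisson 95% interval of 0.163 to 0.675, and DBA/2J had 27 reads, or 1.02 CPM with an interval of 0.674 to 1.49. B6D2F1 stood at 0.974 CPM and D2B6F1 at 0.673 CPM. Sorted by Fgf15, 13 BXD lines lay below and 23 above an empty interval of 0.71 log2 units. By the width of this interval Fgf15 ranked 128 of 14486 genes, under the distance of 1 log2 unit required for the gap genes described next.

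To ask which transcripts followed Fgf15 from line to line, the counts of every gene were regressed on log2 Fgf15 over the 36 lines. Ppfia1, which encodes the scaffold protein liprin-alpha-1, was the only gene associated, and it was lower in the lines with more Fgf15, with a slope of -0.11 ± 0.014 (SE) log2 units per log2 unit of Fgf15 and an adjusted p = 4.39e-05 by edgeR. Ppfia1 averaged 64.4 ± 5.10 CPM (SD, n = 36) and stood at 68.2 CPM in C57BL/6J and 61.9 CPM in DBA/2J. It lies on chromosome 7 beside Fgf15 in the GRCm38.p6 annotation. No such relation was found for the receptors of Fgf15 and their co-receptors. Slopes of Fgfr1, Fgfr2, Fgfr3, Fgfr4, Klb (beta-klotho) and Kl (klotho) lay between -0.031 for Kl (SE 0.082) and 0.025 for Fgfr2 (SE 0.032), and the smallest adjusted p of the 6 was 0.99. A slope of -0.11, as for Ppfia1, lay within 2 SE for Fgfr4 (0.0025, SE 0.14), Klb (-0.0024, SE 0.083) and Kl, so it is not excluded there. For Fgfr1, Fgfr2 and Fgfr3 it lay beyond 2 SE. Fgfr1 averaged 130 CPM, Fgfr2 64.1 CPM, Fgfr3 163 CPM and Kl 12.1 CPM, whereas Klb averaged 1.12 CPM and Fgfr4 0.413 CPM.

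Of 16197 genes tested, 1 passed an adjusted p of 0.05 with edgeR and 1 with DESeq2, and 815 and 834 had an unadjusted p under 0.05. An empty interval parts the lines by Fgf15, although it is under 1 log2 unit wide and the Poisson intervals of single lines overlap across it. Correlations of Ppfia1 with Fgf15 are therefore given on each side and not pooled. Within the 13 lines below the interval Pearson's r was -0.36 (permutation p = 0.229, Spearman's rho -0.34, p = 0.257), and within the 23 lines above it r was -0.23 (permutation p = 0.293, rho -0.12, p = 0.574), and without the 2 lines farthest from the set's median r was -0.068 below and -0.20 above. In the normalized table the same 2 values of r were -0.51 (permutation p = 0.0739, -0.62 without those 2 lines) and -0.31 (permutation p = 0.152, -0.23 without them). No relation inside either set passed a p of 0.05 in either table. These tests could hardly find one, because each set holds few lines over a part of the range of Fgf15. The lower set had only 6 to 14 Fgf15 reads per line, over -1.67 to -0.77 log2 CPM. They therefore do not show that Ppfia1 is unrelated to Fgf15 within a set.

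**Figure D1:**
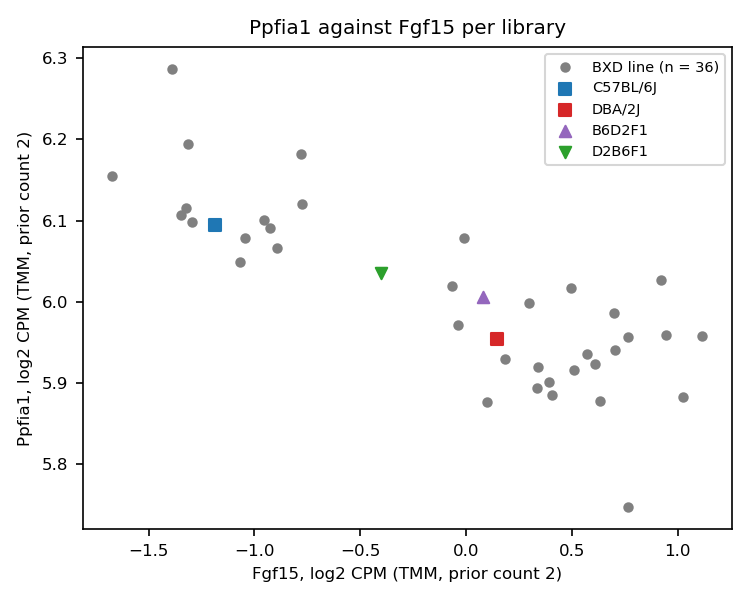
Ppfia1 against Fgf15 in each of the 40 libraries, both as log2 CPM scaled by TMM with a prior count of 2, with gray points for the 36 BXD lines and coloured symbols for the parents and F1 hybrids. The lines fall into 13 with less and 23 with more Fgf15, and the fitted slope over the 36 lines is -0.11.

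Several fixed gene lists leaned one way with Fgf15, though only under the preset correlation of camera. Lines with more Fgf15 had higher values in 18 of 20 endothelial and mural cell genes (adjusted p = 0.33 with an estimated correlation), 15 of 16 genes of the major histocompatibility complex (adjusted p = 0.43 with an estimated correlation) and all 20 interferon response genes (adjusted p = 0.72 with an estimated correlation). The same was true of 13 of 14 meningeal, 16 of 16 striatal and septal and 20 of 22 oxidative phosphorylation genes, and the opposite of 19 of 24 hypothalamic transcription factors and 17 of 20 heat shock and endoplasmic reticulum stress genes, each with an adjusted p = 0.72 with an estimated correlation. Examples were Adora2a, the striatal adenosine receptor, with a slope of 0.39 ± 0.23, Cd74, the invariant chain of MHC class II, at 0.27 ± 0.12, and Foxb1 at -0.12 ± 0.06. Among the heat shock and stress genes, 6 passed when adjusted over the list alone and 0 over all genes. Those were the inducible chaperones Hspa1b (-0.45 ± 0.14) and Hspa1a (-0.27 ± 0.096), Hsph1, the endoplasmic reticulum chaperone Hspa5 and Sdf2l1, which were lower with more Fgf15, and the constitutive chaperone Hspa8 (0.32 ± 0.11), which was higher. Dhcr7, the last enzyme of cholesterol synthesis and another neighbour of Fgf15, passed in its list adjusted over the list alone (0.07 ± 0.021). The preset test called 8 of 30 lists, the estimated one called 0 with 2 at an unadjusted p under 0.05, and fry called 0 with 2.

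The genetic structure of the panel was plain in single genes. In 68 of 14486 genes the 36 lines parted into a low and a high set, separated by at least 1 log2 unit with at least 6 lines on each side, where counts simulated from each gene's own mean and dispersion gave a median of 6 and at most 11 such genes in 20 simulations. Among the genes named by rank, the widest gaps were in Rpl21 (4.43 log2 units, 24 lines below), the cardiac troponin gene Tnnt2 (4.24, 13 below), AA388235 (4.23, 9 below), AI506816 (4.14, 21 below) and Rpl29 (4.08, 18 below). Next came Trim12a (3.95, 14 below), Rps18 (3.70, 9 below), Ccnb1ip1 (3.70, 9 below), Rpl3 (3.61, 20 below), Prss41 (3.33, 26 below), Serpina3m (3.21, 19 below) and the desaturase gene Scd4 (3.11, 21 below). From 12 to 24 lines lay below the gap in 56 of the 68. Ribosomal protein genes made up 6 of the 68, and because these genes have near-identical processed copies elsewhere in the genome their counts are uncertain.

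Some gap genes on the same chromosome split the lines in the same way. Of 50 pairs of gap genes that follow each other along a chromosome, 13 split all 36 lines alike, whichever side was low. The 50 pairs matched in a median of 27 lines and in at least 19, where 2019 pairs on different chromosomes had a median of 20 and a highest of 36. The groups named here were chosen after their values were seen. H2-K1, H2-K2, H2-Q2 and H2-Bl, all class I genes of the major histocompatibility complex on chromosome 17, had the same 9 lines below their gaps, and so did Rps18 and AA388235 on that chromosome. On chromosome 7 the antiviral family members Trim12a, Trim34a and Trim30d shared the same 14 lines, and on chromosome 1 Tnnt2 and the slow troponin gene Tnni1 shared the same 13.

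The parents were set against this pattern to ask whether the sides of a gap follow the parental alleles. C57BL/6J and DBA/2J stood on opposite sides of the gap middle in 56 of the 68 genes (82.4%), with C57BL/6J on the high side in 47 and DBA/2J in 9. Whether the sides reflect transcription or how reads of the DBA/2J allele align to the reference was not tested. Pairs of BXD lines were on opposite sides in a median of 33 genes, with a range of 0 to 52. No pair out of 630 reached 56, which gave a one-sided exact p = 0.00158, the smallest this enumeration can give. Both F1 hybrids lay between the parents in 47 of the 56 genes. In the other 12 of the 68 genes the parents stood on the same side of the middle, which is set on the log2 scale. Among these were Rpl21, Tnnt2, AA388235, Rpl29, Trim12a, Rps18, Ccnb1ip1 and Serpina3m, where the parent at the low end lay inside the gap. In Rpl21 DBA/2J stood at 3.57 log2 CPM between edges of 1.23 and 5.65. Being on the same side there does not show that a gap departs from the parental alleles.

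**Figure D2:**
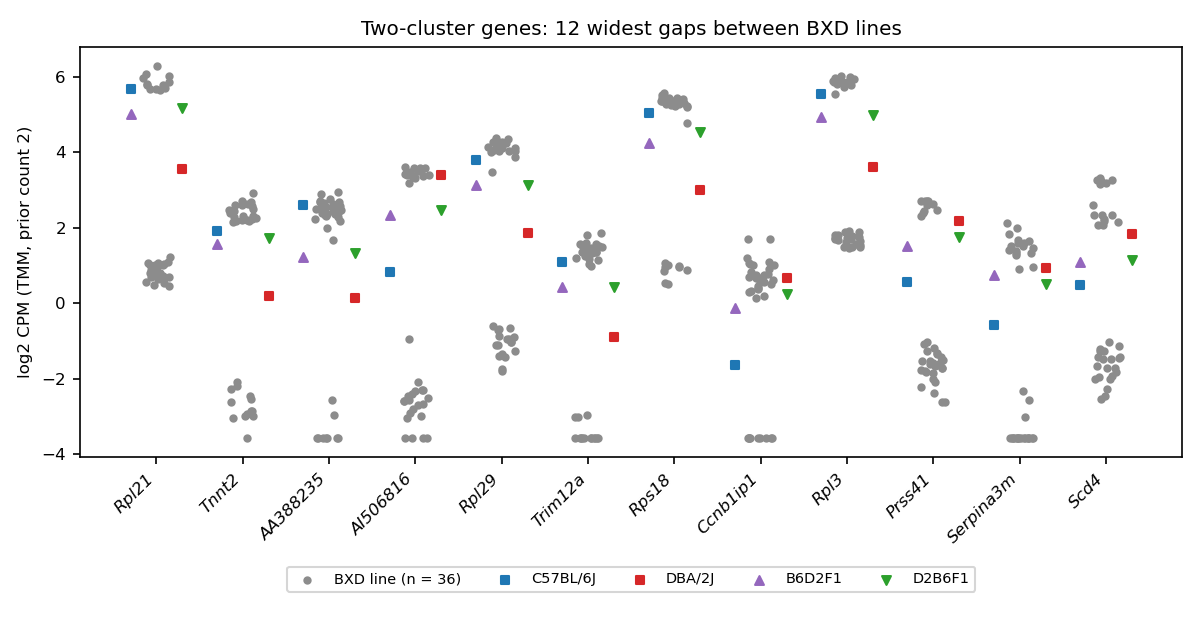
Expression of the 12 named genes with the widest gaps in log2 CPM (TMM, prior count 2), with gray points for the 36 BXD lines and coloured symbols for C57BL/6J, DBA/2J and the F1 hybrids. The gaps run from 3.11 in Scd4 to 4.43 in Rpl21, and in each of the 12 genes both F1 hybrids lie between the parents.

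Between the parents, 77 of 12157 genes (0.633%) differed by at least 1 log2 unit, 59 of them higher in C57BL/6J and 18 higher in DBA/2J. This comparison has 1 library a side and no test. Whether the differences lie in transcription or in the alignment of DBA/2J reads to the reference was not examined. Among the genes named by rank, those higher in C57BL/6J were led by the carbohydrate kinase gene Fggy (log2 2.52, 12.1 against 2.05 CPM), AA388235 (2.46), Rpl21 (2.12), the meiotic cohesin gene Rec8 (2.05), Rps18 (2.02) and H2-Q2 (1.97). Rpl29 and Rpl3 (each 1.93), Myoc (1.92), Sbsn (1.79), the dopamine transporter gene Slc6a3 (1.77, 22.9 against 6.67 CPM) and BC026585 (1.70) followed. DBA/2J was highest over C57BL/6J in Stab2, a scavenger receptor gene, with a log2 difference of -2.69 (18.7 against 121 CPM), although the F1 hybrids had only 2.62 and 1.74 CPM. AI506816 (-2.57), Catsperg2 (-1.73), Pla2g4e (-1.63), Sfi1 (-1.39), Fmo2 (-1.33), Ush1c (-1.32), Hdhd3 (-1.26), Mlycd (-1.23), Fau (-1.21) and Adam33 (-1.21) were also higher in DBA/2J. So was Lars2, the mitochondrial leucyl-tRNA synthetase gene, at -1.26 (1206 against 2886 CPM). Over the lines Lars2 ran from 320 to 13245 CPM and followed Rpph1, the RNA of ribonuclease P (0.174 to 9.65 CPM), a pair chosen after its values were seen. Pearson's r was 0.87 and Spearman's rho 0.75 (each permutation p = 1e-05, the smallest these permutations can give), and r was 0.85 without the 2 lines farthest from the median. A difference of this size in Lars2 thus also arises between lines. Neither of the 2 had a gap, with widest steps of 0.47 log2 units in Lars2 and 0.48 in Rpph1. With 1 library per strain, a strain difference in Lars2 cannot be told from a difference between libraries.

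Genes known to differ between these strains ranged widely. Wdfy1 (-1.02), Alad (-0.93), Gabra2 (-0.76), Glo1 (-0.71) and Nnt (-0.36) were lower in C57BL/6J, and Gpnmb (1.86, 37 against 9 reads) was higher. Ahr (-0.18, counting SE 0.14), Ide (0.08, SE 0.046) and Cyfip2 (-0.02, SE 0.013) lay within 2 counting SE of 0. Other genes of the list were too thinly covered to read a difference. Hc had 28 and 18 reads, Tyrp1 7 and 2, and Taar1 1 and 0. Klrd1 had 0 in both parents, which allows up to 0.118 CPM in C57BL/6J and 0.114 CPM in DBA/2J before TMM scaling. Fgf15 itself differed by -1.33 with a counting SE of 0.56, Fgfr4 by 0.46 (SE 0.53) and Klb by 0.21 (SE 0.35), and Fgfr1 (0.01), Fgfr2 (-0.05), Fgfr3 (0.09) and Kl (0.0018) were nearly the same in both parents.

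Fewer genes separated the parents than separated most BXD lines. Pairs of lines differed in a median of 134 genes, from 36 to 476, and 10 of 630 pairs differed in fewer than the parents did, while the F1 hybrids differed in 5. At most of the wide gaps a parent stood apart from the lines. Over the 37 genes with a gap of at least 2 log2 units, the parent nearer the low end lay inside the gap in 36, and DBA/2J lay below it in Bub1b. The median position of that parent was 0.196 of the linear distance from the lower to the upper edge. In 36 of the 37 genes the parents differed by less than the gap between the lines, for example by 2.12 against 4.43 in Rpl21, so the parental log2 values and counts here hold for these 2 libraries.

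The F1 hybrids were compared with the lines to ask whether expression in the hybrids is intermediate. For the 77 parental-difference genes, B6D2F1 lay in the middle of the parental distance, from 0.25 to 0.75 on the log2 scale, in 76.6% of genes and D2B6F1 in 74.0%. The BXD lines did so in 9.78 ± 3.38% (SD, n = 36), with a range of 1.30 to 16.9%. The difference of 65.5 percentage points had a two-sided exact permutation p = 0.00142, the smallest that 703 arrangements can give. Median positions were 0.52 in B6D2F1 and 0.53 in D2B6F1, where 0 is DBA/2J and 1 is C57BL/6J. B6D2F1 lay between the parents in 88.3% of the 77 genes and D2B6F1 in 89.6%. The BXD lines did so in only 15.6 to 37.7%, so most of their values lay outside the parental range. The low share of the lines in the middle thus does not place them at the parental values. It also depends on the distance between the 2 parental libraries, which was smaller than the gap between the lines at most wide gaps. Both hybrids lay outside the parents in 7 genes, among them Stab2, Sfi1, Ipw, Sgk1 (32.9 and 29.7 CPM against 70.0 in C57BL/6J and 33.9 in DBA/2J), Plin4 (3.93 and 4.13 against 14.7 and 5.38) and Rec8 (3.19 and 5.99 against 25.3 and 6.06). In Ipw they lay on opposite sides of the parents (4.08 and 19.6 CPM against 16.3 and 7.08). B6D2F1 in Sgk1 and D2B6F1 in Rec8 were hardly below DBA/2J, so the 7 are not all clear cases.

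**Figure D3:**
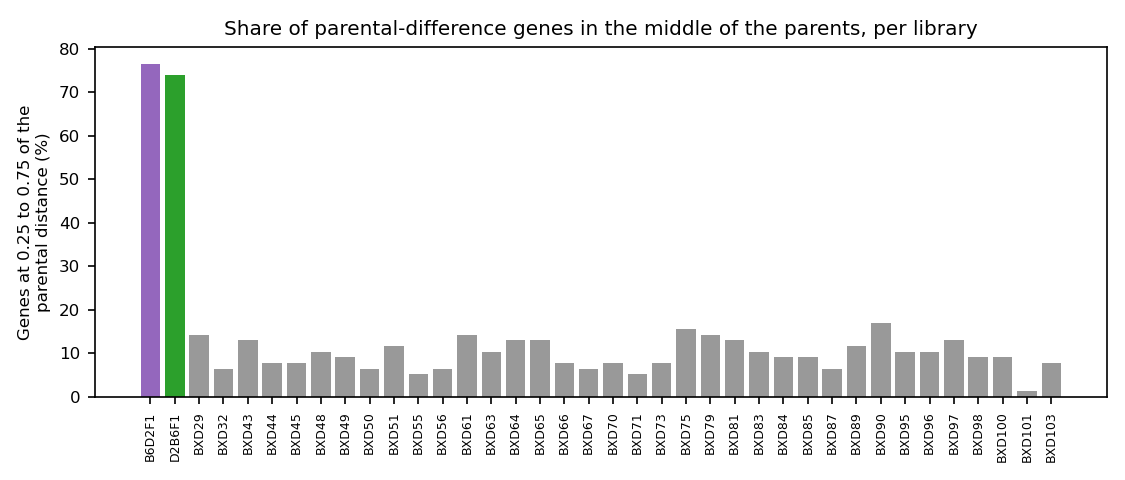
Percent of the 77 parental-difference genes that lie from 0.25 to 0.75 of the log2 distance between DBA/2J and C57BL/6J, with a bar for each library, coloured for the F1 hybrids and gray for the 36 BXD lines. The F1 bars stand at 76.6% and 74.0% and the highest line at 16.9%.

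Reciprocal hybrids share their autosomes and differ in which parental strain gave them the X and Y chromosomes, the mitochondria and the imprinted alleles. Genes of the imprinted Prader-Willi region on chromosome 7 were among the widest apart. Ipw had 4.08 CPM in B6D2F1 and 19.6 in D2B6F1, a log2 difference of -2.24, where C57BL/6J had 16.3 and DBA/2J 7.08 CPM. Snrpn went the other way, with 5.40 against 2.26 CPM (1.22), where C57BL/6J had 3.04 and DBA/2J 5.15 CPM. In both genes D2B6F1, which by the usual naming has a C57BL/6J father, was on the C57BL/6J side. Higher in D2B6F1 were also Scand1 (-1.24), the X-linked Arhgap4 (-0.99, 7.31 against 14.6 CPM), Fbxl15 (-0.90) and Rec8 (-0.89), and higher in B6D2F1 were Capn11 (0.89), Cbl (0.85), Tmem178b (0.85) and Glra1 (0.79). Among genes with at least 5 CPM in a hybrid, 2 of 25 on the imprinted list differed by at least 0.5, namely Snrpn and the paternally expressed Ndn (0.52, 775 against 540 CPM), and 97 of 12126 genes did in all. On the X chromosome the reciprocal difference followed the parental one with r = 0.61 over 7 genes, 85.7% of them with the same sign, which ranked 2 of 20 chromosomes behind chromosome 16 with 4 genes. With a minimum of 1 CPM in place of 5 it was 0.36. The autosomes had a median r of -0.02, from -0.67 to 0.95. These correlations are across genes, which are not independent replicates, and each hybrid was 1 library.

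The F1 hybrids were also tested against all 38 inbred libraries. The gene closest to a call was Ide, the insulin-degrading enzyme, with a mean of 92.2 CPM in the F1 hybrids (105 in B6D2F1 and 79.7 in D2B6F1) and 70.0 CPM in the inbred strains, a log2 difference of 0.40 ± 0.081 (SE) with an adjusted p = 0.23. BXD lines ran from 57.7 to 85.2 CPM. Of 16198 genes 0 passed with edgeR and 0 with DESeq2, with 95 and 93 at an unadjusted p under 0.05. Adjusted over the list alone, Ide passed in the list of genes known to differ between the parents (adjusted p = 1.73e-04), and no member of another list passed. Ide also passed over all genes without D2B6F1 (0.58, adjusted p = 0.0287, where the lone hybrid is assumed to vary like the other libraries) and with 2 principal components in the model (0.41, adjusted p = 0.00072), but stood at 0.19 without B6D2F1, and its adjusted p ran from 0.00072 to 1.00 over the alternatives.

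Under the preset correlation 13 of 30 lists were shifted in the F1 hybrids. Hypothalamic transcription factors were higher in 20 of 24 genes, with a median of 0.19 and examples in Nkx2-4 (0.67 ± 0.44), Nr5a1 of the ventromedial nucleus (0.36 ± 0.24) and Six6 (0.35 ± 0.20) (adjusted p = 0.40 with an estimated correlation). Neuropeptide genes were higher in 22 of 31, with Qrfp at 0.73 ± 0.33, Pomc at 0.40 ± 0.34 and Crh at -0.28 ± 0.17 (adjusted p = 0.57 with an estimated correlation). Also higher were 17 of 20 immediate early, 20 of 24 ribosomal protein and 14 of 19 tanycyte and ependymal genes (each adjusted p = 0.53 with an estimated correlation). The known-to-differ list had 6 of 12 genes higher and was shifted up in the test and the mean although its median was -0.0051 (adjusted p = 0.27 with an estimated correlation). Interferon genes were lower in 20 of 20, for example Oas1a at -1.10 ± 0.49 (adjusted p = 0.40 with an estimated correlation), and meningeal genes in 14 of 14 (adjusted p = 0.74 with an estimated correlation). Striatal and septal genes were lower in 14 of 16, endothelial and mural genes in 19 of 20, glucocorticoid-responsive genes in 13 of 15, microglial genes in 15 of 18 and MHC genes in 14 of 16, each with an adjusted p = 0.53 with an estimated correlation. The estimated test called 0 lists, with 3 at an unadjusted p under 0.05, and fry called 0 with 1.

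All 4 parental and F1 libraries were set against the 36 BXD lines. No gene passed the test. Ide again came closest, at 84.4 CPM in the parental and F1 libraries against 69.6 CPM in the lines (log2 0.28 ± 0.062 SE, adjusted p = 0.54). It was called with 2 principal components in the model (0.29, adjusted p = 0.0047) and stood at 0.16 without B6D2F1, with adjusted p-values from 0.0047 to 1.00 over the alternatives. The count was 0 of 16198 with edgeR and 0 with DESeq2, with 163 and 155 at an unadjusted p under 0.05. In simulated data of this shape edgeR recovered 95.5% of genes changed by 1 log2 unit and 76.1% of those changed by 0.5. The simulated genes were drawn independently, without structure shared between genes, so these shares may not hold for the real libraries.

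By list, interferon response genes were lower in the parental and F1 libraries in 20 of 20 genes, with a median of -0.25 and a preset adjusted p = 1.68e-10 (adjusted p = 0.35 with an estimated correlation). Members ranged from Oas1a (-0.58 ± 0.34), Ifi44 (-0.52 ± 0.33) and Trim30a (-0.49 ± 0.15) to Isg15 (-0.0065 ± 0.20). MHC genes were lower in 14 of 16, among them the class II genes H2-DMb1 (-0.91 ± 0.49), H2-Aa (-0.86 ± 0.51) and H2-Ab1 (-0.81 ± 0.48) (adjusted p = 0.35 with an estimated correlation). Immediate early genes were higher in 17 of 20, with Fosb at 0.28 ± 0.23 and Egr3 at -0.20 ± 0.32. Glucocorticoid-responsive genes were higher in 12 of 15, with Plin4 at 0.41 ± 0.22, and ribosomal protein genes in 18 of 24, while microglial genes were lower in 15 of 18 (each of these 4 lists adjusted p = 0.59 with an estimated correlation). Endothelial and mural genes were lower in 16 of 20 (adjusted p = 0.67 with an estimated correlation) and thalamic genes higher in 13 of 18 (adjusted p = 0.78 with an estimated correlation). The preset test called 8 of 30 lists, the estimated one 0 with 3 at an unadjusted p under 0.05, and fry 0 with 0. Adjusted over the list alone, Ide passed among the genes known to differ between the parents (adjusted p = 5.78e-04) and Ndn among the imprinted genes (-0.35 ± 0.10, adjusted p = 0.032), and no member of another list passed.

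Gene groups differed in how they varied from line to line. Of 12015 genes with a mean of at least 5 CPM the median SD over the 36 lines was 0.13 log2 units, where reads alone would give 0.050, and 219 genes (1.82%) exceeded an SD of 0.5. The most variable of the genes named by rank were Fggy (3.16), Rpl29 (2.66), Rpl21 (2.41), Ttr (2.24), Rpl3 (2.11), Rec8 (1.98), Rps18 (1.97), Myoc (1.92), Eps8l1 (1.87), Sbsn (1.84), Capn11 (1.81) and H2-Q2 (1.68). Ttr, the transthyretin gene of the choroid plexus, stood at 814 CPM in BXD32, 78.9 in BXD65, 49.8 in BXD101 and 22.1 in BXD63, against a line median of 1.20.

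In 18 of 30 lists the genes varied more than in matched random lists and also varied together. With 1 library per line, variation between lines in any list cannot be told from variation in dissection or between libraries. Meningeal and fibroblast genes had a median SD of 0.61 and a mean pairwise r of 0.75 over the lines, with the transporter gene Slc22a6 at 0.574 to 9.87 CPM and Ogn at 2.30 to 25.2 CPM. Striatal and septal genes had an SD of 0.40 and r of 0.71, with Adora2a at 0.957 to 41.8 CPM and the DARPP-32 gene Ppp1r1b at 9.79 to 183 CPM. Thalamic genes had an SD of 0.37 and r of 0.53 (Prkcd 14.9 to 109 CPM), and myelin genes an SD of 0.22 and r of 0.59 (Mbp 1422 to 3548 CPM). Interferon response genes (0.38, r 0.48, Ifi44 0.457 to 2.49 CPM) and immediate early genes (0.34, r 0.46, Egr4 0.876 to 7.12 CPM) also varied together. Each of these 6 lists had adjusted p-values of at most 0.00069 for spread and 0.00025 for r. Lower but called coherence was seen for MHC genes (r 0.29), ribosomal proteins (0.29), oxidative phosphorylation (0.27), glucocorticoid-responsive genes (0.23), hypothalamic transcription factors (0.23), microglia (0.20), endothelium (0.20), pituitary (0.19), tanycytes and ependyma (0.19), telencephalon (0.18) and choroid plexus (0.12), all called for spread as well. Neuropeptide genes had an SD of 0.29 and r of 0.22, with Oxt (oxytocin) at 17.1 to 133 CPM, Avp (vasopressin) at 34.2 to 163 CPM and Npvf at 1.31 to 11.1 CPM. Pituitary Gh reached 24.3 CPM in BXD85 and 19.3 in BXD32. In BXD32 and the other 3 lines with high Ttr the choroid plexus list is affected, and without them its mean r was -0.015 (adjusted p = 0.69).

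Some lists varied without moving together. The neurotransmitter identity genes had a median SD of 0.31 and a mean r of -0.00071, with Slc17a7, the vesicular glutamate transporter of the cortex, at 1.62 to 73.0 CPM, and the known-to-differ genes had 0.38 and -0.017. Imprinted genes (SD 0.17, r 0.036) and oligodendrocyte precursor genes (0.18, r 0.076) were called for spread alone. Heat shock and stress genes (r 0.32), sex-linked genes (0.34), cholesterol synthesis (0.22) and the circadian clock (0.080) were called for r alone. Astrocyte genes, glucose and energy sensing genes, hormone and neuropeptide receptor genes and the FGF list were called for neither. The FGF list had a median SD of 0.17 against 0.15 in random lists (adjusted p = 0.17) and a mean r of 0.0021 (adjusted p = 0.39). In all, 22 of 30 lists were called for spread and 22 for r.

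**Figure D4:**
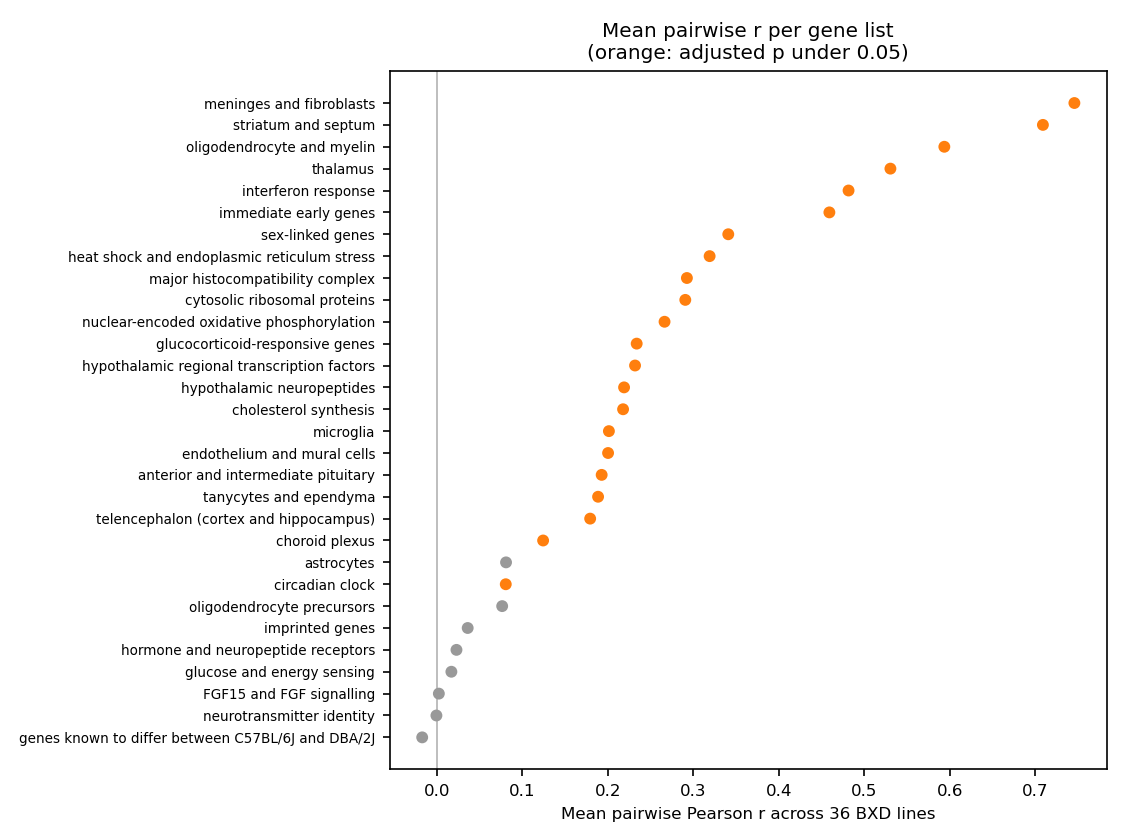
Mean pairwise Pearson r of the genes of each of the 30 lists over the 36 BXD lines, with a point per list, orange where the adjusted p against matched random lists is under 0.05 and gray elsewhere. Meningeal genes at 0.75 and striatal and septal genes at 0.71 lie farthest from 0, and the FGF list lies at 0.0021.

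The parents were also compared by list, with the 630 pairs of BXD lines as a scale for the median difference of a list. Genes known to differ between the parents had a median log2 of -0.27 (C57BL/6J over DBA/2J), and 6 pairs of lines were as far apart. That list was chosen for differing between these strains, so its place is no independent result. Glucocorticoid-responsive genes stood at 0.31, for example Sgk1 at 70.0 against 33.9 CPM and Plin4 at 14.7 against 5.38 CPM, with 29 pairs (4.60%) as far apart. In the other 28 lists more than 5% of pairs were as far apart as the parents. With 30 lists, a share just under 5% in a single list can arise by chance. Cholesterol synthesis genes (-0.19, 53 pairs), imprinted genes (-0.084, 134 pairs), immediate early genes (-0.39, 187 pairs, Fos 27.1 against 52.9 CPM) and interferon genes (-0.23, 324 pairs) had lower medians in C57BL/6J. Heat shock and stress genes (0.21, 138 pairs, Hspa1b 4.82 against 1.40 CPM), myelin genes (0.20, 255 pairs, Mobp 393 against 239 CPM) and thalamic genes (0.33, 289 pairs, Prkcd 48.6 against 28.3 CPM) had higher ones. Each parent was 1 library, so these differences hold for the libraries and were not tested between strains.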

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

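The tests of the genes beside Fgf15, of the additional transcript, of marker scores as an explanation and of shuffled Fgf15 values were chosen or read after the result was seen, while the fit with 3 marker scores was itself fixed before the data were examined.

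A signal appeared in data no comparison used. The normalized table holds 2 names that the raw table lacks, and the transcript ENSMUST00000168966 is one with a median of 53 recovered reads per library (7 to 156), well above the limit of 3 that a count of 0 allows. Its name is absent from the GENCODE vM21 annotation, so what it encodes was not settled. Sorted over the 36 lines it had a gap of 1.42 log2 units with 13 lines below and 23 above, and 36 of 36 lines lay on the side that Fgf15 gave them. Its normalized value was 18.4 in C57BL/6J, 64.6 in DBA/2J, 47.2 in B6D2F1 and 31.3 in D2B6F1. Within the sets its r with Fgf15 was 0.27 (permutation p = 0.374, 13 lines) and 0.48 (permutation p = 0.0195, 23 lines), and 0.20 and 0.35 without the 2 lines farthest from the median. With Fgf15 taken from the normalized table as well, r was 0.088 (permutation p = 0.770) and 0.47 (permutation p = 0.0244). The other name, ENSMUST00000033389, carries the same values as Fgf15 in every library.

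Some genes beside Fgf15 followed it. Of the 15 tested genes nearest to Fgf15 on chromosome 7, 7 (46.7%) had an unadjusted p under 0.05 for the slope on Fgf15, namely Ppfia1, Dhcr7, Fgf3, Oraov1, Ccnd1, 1810010D01Rik and Mrgprf. Of the 7 slopes 3 were negative, and Ppfia1 alone passed the adjustment over all genes. In 31621 other windows of 15 genes the median was 1 gene and the highest 7. With the gene of the smallest p left out of each window, which removes Ppfia1, 6 of 14 genes (42.9%) remained beside Fgf15, and 3 of the other windows had as many. Variation linked to this region is a candidate explanation, and whether it acts on transcription or on how reads of the DBA/2J allele align to the reference was not tested. The cell makeup of the dissected pieces stays open. With scores of choroid plexus, thalamus and myelin genes in the model the slope of Ppfia1 was -0.1073 (adjusted p = 1.06e-04), but these scores explained only 1.12% of the variance of Fgf15 and could hardly move it. With scores of endothelial, meningeal, striatal and hypothalamic regional genes it was -0.1068 (adjusted p = 8.13e-04). These explained 20.7% of the variance (p = 0.116), so their relation to Fgf15 was not established either. Over 12 alternatives the adjusted p ran from 1.10e-09 to 8.74e-04. By the number of genes called, chance could not be excluded, because 12 of 100 shuffles of Fgf15 over the lines, the real order included, gave at least the 1 gene of the real order, and the highest other gave 104. With 1 line left out that shuffle gave from 2 genes without BXD45 to 660 without BXD64. Counts this large point to a structure among the lines, and what makes it was not tested. The smallest p of the real order, 5.41e-09, was below that of every other shuffle (2.97e-08).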

How the results depend on the processing

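Fits on recovered reads, with 4 marker scores and without the 4 libraries with high Ttr were chosen after seeing the data, and the other alternatives before. Of the results that answer a comparison, 50 alternatives stayed on the same side of the test, within 1.5 times for a count or inside the 95% interval for r, and 13 moved. That interval is wide, since r on the X chromosome fell from 0.61 to 0.36 at a minimum of 1 CPM. With 2 principal components 1 gene was called between BXD lines and parental and F1 libraries and 1 between F1 and inbred libraries, and leaving out 1 hybrid gave 0 to 1 there, the 1 without D2B6F1. That gene was Ide each time (0.29, 0.41 and 0.58), and the cause was not tested. The Fgf15 fit called 4 genes with every gene kept, adding Apob, Cyp3a11 and Cyp7a1, which the filter on low counts removes, and 3 on recovered reads, adding both transcripts absent from the raw table. With an estimated correlation the list shifts went from 8, 13 and 8, or 29 in all, to 0, and the cause was not tested. The parental count was 228 at a minimum of 1 CPM and 11 at 2 log2 units, and the gap genes were 129 at a gap of 0.7 and 39 at a mean of 5 CPM, each by looser or stricter rules. Slopes on Fgf15 near 0 and never called turned sign, and the cause was not tested. Without the high-Ttr libraries they were 0.0127 for Fgfr1, -0.0101 for Fgfr4, 0.0316 for Klb and 0.0113 for Kl. With 2 principal components they were 0.00181 for Fgfr3 and 0.00088 for Kl, with library size -0.0165 for Fgfr4 and 0.0095 for Klb, and with 3 marker scores 0.00021 for Klb. With 4 marker scores they were -0.0071 for Fgfr2, 0.0201 for Fgfr3 and 0.00125 for Klb. Without the 2 farthest lines they were -0.124 for Fgfr4 and 0.0120 for Klb, and with 40 libraries -0.0437 for Fgfr4. Kl differed between the parents by -0.0028 in the normalized values and 0.0018 in the counts. Among single genes 170 other alternatives kept their direction and call. Depth limits Fgf15, which had 6 to 66 reads per line, and Fgfr4 and Klb, with means of 0.413 and 1.12 CPM.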

Other observations

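The tests of the parents inside the gaps and of the Ttr lines were chosen after the result was seen, as was the reading of the splits.

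In the neurotransmitter identity list, whose genes did not vary together, 3 members chosen after their values were seen ran over wide ranges. Tph2, the serotonin-synthesizing enzyme of the raphe, ran from 0.191 to 12.9 CPM, Chat of cholinergic neurons from 2.08 to 21.2 CPM, and the dopamine transporter gene Slc6a3 from 3.61 to 75.6 CPM. The class I gene H2-K1 ran from 3.39 to 38.8 CPM. Gpnmb, which carries a nonsense variant in DBA/2J, had a gap of 2.37 log2 units with 15 lines below. Other genes with a gap, chosen after their values were seen, were the nuclear RNA Neat1 (1.34, 18 lines below), the nicotinic receptor gene Chrna3 (1.01, 19 below), Myo7a (2.74, 16 below) and Ipw (1.43, 17 below). Both hybrids lay at the low edge of the gap in Bub1b although C57BL/6J was at the high one, with positions of -0.13 and -0.14 in the hybrids and 0.96 in C57BL/6J.

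C57BL/6J and DBA/2J lay inside most of the wide gaps of the lines. Over 37 genes with a gap of at least 2, the parent at the low end lay from 0.05 to 0.45 of the linear distance in 28 of 31 genes for DBA/2J (90.3%) and in 6 of 6 for C57BL/6J, while no BXD line exceeded 5.56% when left out of the lines that define the gaps. The exceptions were Bub1b (-0.052), Fggy (0.012) and Tnni1 (0.67). Heterozygous segments shared by all animals of a library are argued against, because 34 of the 37 genes showed the pattern and the F1 hybrids had medians of 0.60 and 0.65, far from the parents' 0.196. At least 1 gene showed it on 15 of 15 chromosomes (100%), a share that could hardly be lower with 34 such genes. The number of animals behind these 2 libraries is not stated, so heterozygous animals among others in a pool are not excluded. Expression of the low allele that differs gene by gene is argued against too, since the positions were alike across genes, with an interquartile range 43.3% of their median. RNA or reads of the other parent in each of the 2 libraries may account for it, as a hypothesis found and tested on the same data. It would make the parental differences in the report smaller than those between the strains, and no other biological explanation was tested.

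Ttr marks 4 BXD lines. Of the 15 other choroid plexus genes 9 were highest in BXD32, the line with the most Ttr, which argues against a difference in Ttr alone in that line. The summed excess of the 9 genes with a median under 2 CPM argues against it in BXD65 and BXD101 too, since 0 of 496 pairs of the 32 lines without high Ttr had as much as these 2 lines (5.19 and 5.22 CPM). In BXD63 (1.19 CPM) it stays open, because 5 of those 32 lines had as much. In BXD32 Kcne2 had 7.09 CPM, F5 8.83 CPM and Kcnj13 5.13 CPM against line medians of 0.473, 1.14 and 0.673. Choroid plexus tissue in the dissected pieces could account for it, but the summed excess of the 9 genes in the other 3 lines was 11.6 CPM against 5.77 predicted from BXD32, a ratio of 2.01 at the edge of the range set for it, so the test did not decide. No other biological explanation was tested.

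For the count of genes between BXD lines and parental and F1 libraries the other splits decide nothing about chance. The real split called 0 with edgeR (163 at an unadjusted p under 0.05, and 0 with DESeq2), so 100 of 100 splits into 36 and 4 were bound to give at least as many. The highest other split called 3057, the next 186, and 66 called 0. The split with 3057 set BXD32, BXD43, BXD45 and BXD75 against the rest. Its count was 2 without BXD32, 55 without BXD43, 4143 without BXD45 and 5322 without BXD75, which points to a structure of the samples beyond the labels that rests on BXD32 and BXD43 in this split.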
